A study of Mus musculus with 6 samples.

How the data were processed

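Total RNA from endothelial cells of 3 control and 3 MFAP5 plugs was amplified into biotin-labelled cRNA and hybridized to 1-colour Affymetrix Mouse Genome 430 2.0 arrays, per the labels' protocols and the series' design text. How endothelial cells were separated from other cells of the plugs is not given in the sources used here. MAS5 is the tool that the submitters' processing notes name; its scaling target and any later normalization are not given in the sources used here. The deposited values were log2 signals, as read from the values: they were positive and negative, every probe set had a median of 0 over the 6 arrays to within 5e-07, and the widest probe set spanned 8.24 units, more than the range of an array scanner allows at a base of 10. A natural log was not excluded, and then every log2 difference and fold printed would be too small. Higher values were taken to stand for more signal, which the sources used here do not state. Centring removed the level of each probe set, so no filter on dim probe sets, no offset and no detection call could be applied, and it left differences between arrays untouched. Array medians were computed over all 45101 probe sets.

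The 64 control probe sets of the array were left out of the tests, leaving 45037. Gene names came from the platform annotation supplied with the value table, in which 34945 of the tested probe sets had 1 gene symbol, 932 had several and 9160 were not listed; the last are unnamed here, which does not mean that they lack a gene. Symbols were updated through the Entrez identifier in a RefSeq gene table (GRCm38.p6), which held 34754 of the probe sets with 1 symbol, and no coordinates were used. A gene's value was the mean of its probe sets with 1 symbol, which gave 18193 genes, 9010 of them with more than 1 probe set.

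Groups were compared with limma (version 3.58.1, R version 4.3.3; lmFit and eBayes without a trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05) on all probe sets and on all genes. Differences are MFAP5 minus control. This departs from the plan written before the data were examined, which assumed signals with a level: the plan had an offset of the log, a filter at the median level, a variance trend on the mean level and the brightest probe set of each gene. Gene lists fixed before the data were examined (35 lists with 803 different genes, of which 756 were measured under a name) were tested with camera with a preset correlation of 0.01, adjusted over the 34 lists with at least 5 genes, with camera with an estimated correlation and with fry. Camera compares a list with all other genes, whose median difference was -0.08, while fry asks whether a list's genes moved 1 way. With a preset correlation 10 lists were called higher and 4 lower; with an estimated correlation none was, with a lowest adjusted p of 0.244, and fry called 5, all of them among the 14. Single values of control probe sets were compared by exact permutation of 3 against 3 arrays, two-sided, where the smallest possible p is 0.1.

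The genes named were, by a rule written before the data were examined, the 12 higher and 12 lower genes with the largest log2 difference among those past the threshold, with non-overlapping groups and a named gene model; up to 4 members of each list with the smallest p; and 12 genes of interest, of which 11 had a probe set with 1 symbol. Ptk2 had none and is not analysed here. Il1a, the exception to a count, was chosen after its values were seen. Additional lists were written after the first results. Their genes, unless also named by the rule above, and 2 genes chosen after their values were seen appear only among the additional observations.

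The procedure was tested on simulated data: normal noise with each probe set's own spread within groups for 45037 probe sets, of which 200 were changed. Of 50 probe sets changed by a log2 difference of 0.5, 2.0% were recovered, of 50 changed by 1, 44.0%, of 50 changed by 2, 90.0%, and of 50 changed by 3, 98.0%, with 2 false calls among 119. On simulated values of 18193 genes a shift of 0.5 planted in the interferon list was called, and none of the other 33 lists was. Noise was drawn independently for each probe set, so the simulated genes were not correlated. In the data, estimated correlations within the lists ran from -0.050 to 0.77. The simulation therefore does not show how often camera with a preset correlation of 0.01 calls lists falsely in such data.

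Alternatives were quantile normalization, median centring of each array, eBayes with a trend on the mean of the centred values, which carries no signal level, array weights, the replicate number as a block, leaving out each sample in turn, a minimum log2 difference of 1, an unmoderated statistic and the set tests above. Added after the data had been seen were the spike-in level of each array (mean of 14 probe sets for bacterial transcripts bioB, bioC and bioD) as a covariate, control replicate 1 as the sole control, the 50% of probe sets with the larger SD, and the probe set with the largest SD for each gene.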

Results

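Gene expression was measured in endothelial cells taken from Matrigel plugs, gels of basement membrane proteins, that had been placed in the peritoneal cavity of nude mice. The plugs either held recombinant microfibrillar-associated protein 5 (MFAP5), a secreted glycoprotein of elastic microfibrils, or lacked it. Each of the 2 groups had 3 samples, each on 1 Affymetrix Mouse Genome 430 2.0 array. The labels call the samples independent without saying whether each came from its own animal. The limma p-values and SEs below therefore measure the spread between these samples, pooled in part over probe sets or genes. A printed SE is thus not that of the 3 samples per group alone, and can be smaller or larger than it. Camera p-values with a preset correlation rest largely on the spread across genes, and Fisher's test on counts of probe sets. The comparison asked which transcripts differed in endothelial cells that had entered a gel holding MFAP5. The values were relative: each probe set was centred on its median over the 6 arrays, so differences between arrays could be read and absolute levels could not. The log base was taken as 2, and every fold below rests on that. The medians of the 3 control arrays were -0.012, 0.049 and 0.027, and those of the MFAP5 arrays were -0.026, 0 and -0.014. The number of arrays limits the precision.

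The lower genes with the largest changes were Retn, which encodes the adipokine resistin, at a log2 difference of -5.51 ± 0.97 (SE, n = 3 per group; limma adjusted p = 0.0194), and Cidec, a lipid droplet protein, at -5.35 ± 0.65 (adjusted p = 0.00318). Among the next were Plin4, a perilipin of lipid droplets, at -4.03, G0s2, an inhibitor of adipose triglyceride lipase, at -3.96, and Dgat2, the enzyme of the last step of triglyceride synthesis, at -3.65. Reep6 (-4.61), Cdo1, a cysteine dioxygenase (-4.17), Tmem45b (-4.14), Car3, a carbonic anhydrase of fat and muscle (-3.77), Wfdc21 (-3.72), Thrsp, a lipogenic regulator (-3.62), and Pnpla3, a lipid droplet protein (-3.62), completed the 12 lower genes, with adjusted p between 9.93e-05 and 0.0410. The MFAP5 samples differed in size: Retn stood at -6.27, -3.71 and -1.43 in replicates 1, 2 and 3, and its difference was -4.28 without replicate 1 and -6.70 without replicate 3. Leaving out the same 2 samples gave -4.71 and -6.25 for Cidec, -3.44 and -4.97 for Plin4, and -2.76 and -4.73 for Car3. Without MFAP5 replicate 3, G0s2, Tmem45b and Wfdc21 were at -4.79, -4.79 and -4.63. The probe sets of Thrsp disagreed in size, at -6.71, -3.82 and -0.35, and the last of them did not pass the threshold. The 4 probe sets of Car3 lay between -5.12 and -2.01, and 2 of them passed.

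The higher gene with the largest change was Il6, the cytokine interleukin 6, at 2.61 ± 0.55 (SE, n = 3 per group; adjusted p = 0.0407). MFAP5 replicate 2 had an Il6 signal of 0.49 where replicates 1 and 3 had 2.64 and 3.01, and without it the difference was 3.39. Stmn4, of the stathmin family of microtubule regulators, was higher by 2.13 and Cxcl2, a chemokine that attracts neutrophils, by 2.12. Pmaip1, a pro-apoptotic BH3-only protein, was higher by 1.98, and Nr4a1, an orphan nuclear receptor and immediate early gene, by 1.80. The 12 higher genes also held Slfn4 (1.70), Tnfaip6, a hyaluronan-binding protein (1.66), Tmtc2 (1.63) and Tcim (1.63). The rest were Nfkbiz, a member of the inhibitor kappa B family (1.61), Gzme, a granzyme (1.60), and Atf3, a stress-induced transcription factor (1.58). The limma adjusted p of the 12 lay between 0.00718 and 0.0407. In each of these 24 genes the 3 MFAP5 values lay on the same side of the 3 control values, as the naming rule required. With control replicate 2 left out, 1 of the 12 higher and 7 of the 12 lower genes passed the threshold, and without control replicate 3 the counts were again 1 and 7. Without MFAP5 replicate 1, 6 of the 12 higher genes passed. With a variance trend on the mean of the centred values, which is not the trend on signal level first planned, 3 of the 12 higher and 6 of the 12 lower genes missed the threshold, among them Il6 (adjusted p = 0.997), Nr4a1 (0.532), Retn (0.608), Wfdc21 (0.413), Car3 (0.372), Plin4 (0.190), G0s2 (0.177), Cidec (0.119) and Stmn4 (0.0775). Stmn4 also missed it with quantile normalization (adjusted p = 0.0638). With the spike-in level described below as a covariate, 1 of the higher and 7 of the lower genes passed, while all kept their direction, at sizes of 1.37 to 2.62 and 3.51 to 5.32. All 24 kept their direction whichever sample was left out. The lack of overlap that the naming rule required fixes this result in advance, so it is no sign of stability.

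**Figure D1:**
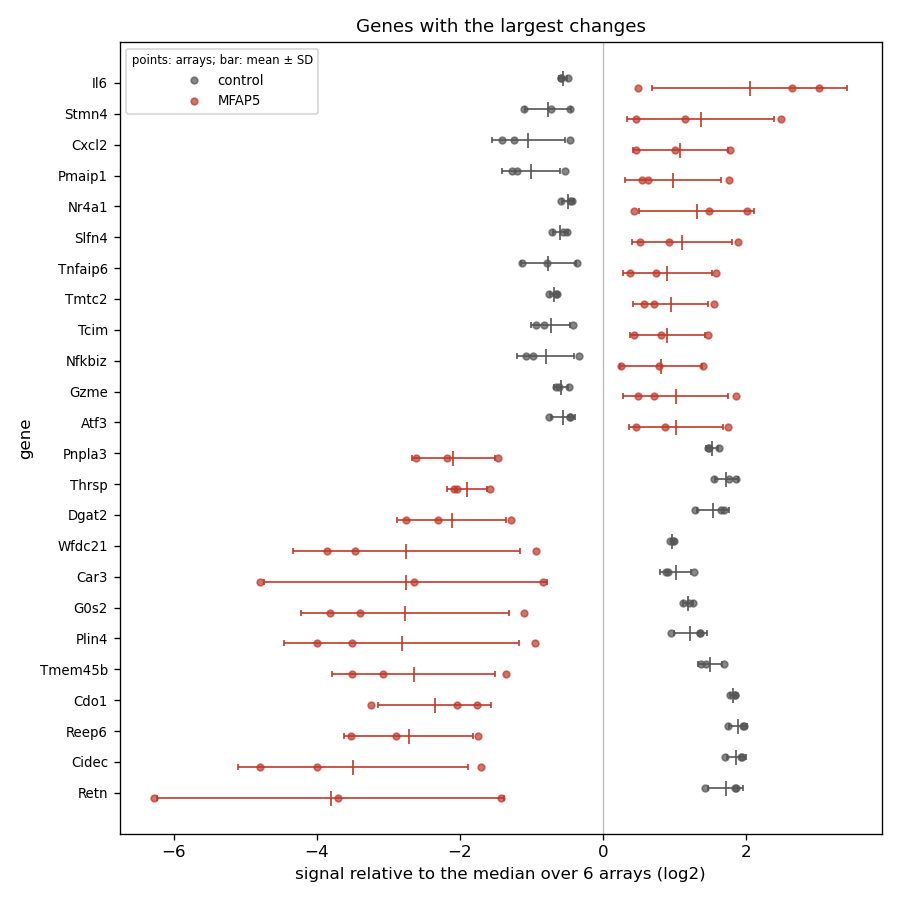
Signal of the 12 higher and 12 lower genes with the largest changes, relative to each probe set's median over the 6 arrays (log2, horizontal axis), 1 row per gene; points are arrays (3 control, 3 MFAP5), and bars the group mean ± SD. Differences run from 2.61 for Il6 to -5.51 for Retn, and the MFAP5 arrays of the lower genes are spread more widely than the control arrays.

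In all, 704 of 45037 probe sets were higher and 774 lower with MFAP5 (limma, adjusted p under 0.05), and 8420 had an unadjusted p under 0.05. The unmoderated statistic called 0 probe sets after adjustment, with 6433 at an unadjusted p under 0.05. By gene, limma called 138 of 18193 higher and 508 lower. Of these, 44 of the higher and 209 of the lower genes changed at least 2-fold, and 25 genes were at least 8-fold lower. The groups did not overlap in 23.2% of probe sets, where chance gives 10%. These counts depended on single samples: without control replicate 1 there were 2821 higher and 3369 lower probe sets, without control replicate 2 138 and 291, and without control replicate 3 90 and 251. Without MFAP5 replicates 1, 2 and 3 they were 342 and 405, 612 and 500, and 364 and 553. The gene counts without control replicates 1, 2 and 3 were 760 higher and 1914 lower, 16 and 230, and 14 and 205, and without MFAP5 replicate 1 they were 68 and 295. Control replicate 1 stood apart from the other two controls: across probe sets, which are not independent replicates, its correlation was -0.028 with control replicate 2 and 0.020 with control replicate 3, which correlated with each other at 0.69. The hybridization spike-ins, bacterial transcripts added to each hybridization, had mean relative signals of -0.32, 0.64 and 0.65 in the 3 control arrays and -0.038, -0.0078 and -0.0065 in the MFAP5 arrays (exact permutation test, two-sided, p = 0.4).

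Of 12 measured adipocyte markers 10 fell (12 when adjusted over the list alone), and all 12 had a lower mean with MFAP5, with a median log2 difference of -2.81. The shift passed camera with a preset correlation of 0.01 (adjusted p = 4.70e-15), had an adjusted p = 0.262 with an estimated correlation, and passed fry (adjusted p = 0.0229). Lep, which encodes leptin, was at -3.02 ± 0.20, Slc2a4, the insulin-responsive glucose transporter, at -2.60 ± 0.13, and Pparg, the nuclear receptor of adipocyte differentiation, at -2.45 ± 0.25 (SE, n = 3 per group; adjusted p = 3.07e-04, 1.42e-04 and 0.00146). The 3 control arrays had list medians of 0.98, 1.16 and 1.17, and the MFAP5 arrays -1.82, -1.61 and -0.86. When control replicate 2 or 3 was left out, 7 members passed in each case.

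Of 18 neutrophil markers 6 fell (10 when adjusted over the list alone). The neutrophil median was -0.52 (camera adjusted p = 1.05e-05, adjusted p = 0.262 with an estimated correlation, fry adjusted p = 0.0229), and the arrays' medians were 0.14, 0.42 and 0.33 in the controls and -0.29, -0.22 and -0.30 with MFAP5. Among the 6 were S100a8, a calcium-binding protein abundant in neutrophils, at -1.63 ± 0.12, S100a9 at -1.22, Clec4e at -1.43 and the gelatinase gene Mmp9 at -0.87. G0s2, named above among the 12 lower genes, was a member of this list. Its signals of -3.81, -3.40 and -1.11 in MFAP5 replicates 1, 2 and 3 had the replicate order of the adipocyte medians. Whether its call reflects neutrophils was not tested. Of 29 oxidative phosphorylation genes 8 fell (17 when adjusted over the list alone), such as the complex III subunit Uqcrfs1 at -0.67 ± 0.10 and the complex I subunit Ndufs1 at -0.63 ± 0.11, with a list median of -0.29 (camera adjusted p = 5.01e-06, adjusted p = 0.302 with an estimated correlation, fry adjusted p = 0.0229). Without control replicate 2 or 3 none of these 8 calls was made by limma, with 5594 and 5326 probe sets at an unadjusted p under 0.05, and without MFAP5 replicate 1 or 2 it made 1. Of 41 cell cycle genes 3 fell (14 when adjusted over the list alone), Kif20a, Ccnb2 and Plk1, which act in mitosis, at -0.79, -0.63 and -0.81. The cell cycle median was -0.31 (camera adjusted p = 1.48e-04, adjusted p = 0.683 with an estimated correlation, fry adjusted p = 0.133), and the list passed camera with every left-out sample except control replicate 1 (adjusted p = 0.0550). Its count of lower genes was 10, with 2 higher, without control replicate 1, 6 without MFAP5 replicate 3 and 0 with any other sample left out. With the spike-in level as a covariate limma called 2 oxidative phosphorylation genes lower and no cell cycle gene, with 6744 probe sets at an unadjusted p under 0.05, while the list medians were -0.32 and -0.28. All 12 adipocyte markers were lower in the same 3 arrays as these groups, and the ratio of 3' to 5' probe sets of beta-actin was higher there without overlap. Here and in the paragraphs below these 3 arrays are the whole MFAP5 group, so every difference between the groups shares them. The Gapdh ratio overlapped between the groups (difference 0.081, exact permutation test, two-sided, p = 0.4).

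Of the 34 genes on the list of ERK signalling and immediate early genes, 13 rose and none fell (24 and 1 when adjusted over the list alone), and the median log2 difference was 0.63. The list had a camera adjusted p = 7.65e-21, an adjusted p = 0.262 with an estimated correlation and a fry adjusted p = 0.0343. The zinc-finger factor gene Egr3 rose by 1.24 ± 0.14, Dusp5, an ERK phosphatase, by 1.24 ± 0.18, the Kruppel-like factor gene Klf6 by 0.98 ± 0.14 and Ier3 by 0.69 ± 0.10 (SE, n = 3 per group; adjusted p = 0.00230, 0.00839, 0.00724 and 0.00838). Leaving out control replicate 2 or 3 left 3 members past the threshold, and without MFAP5 replicate 1, 8 did. Without MFAP5 replicate 2, 15 were higher and 1 lower. The list of heat shock and dissociation stress shares 8 members with the last. Of its 24 genes 7 rose and none fell (13 rose and 1 fell when adjusted over the list alone). Those that rose included the inducible chaperone gene Hspa1b at 1.45 ± 0.19 and Egr1 at 0.66 ± 0.13. The median of this list was 0.41 (camera adjusted p = 6.81e-13, adjusted p = 0.244 with an estimated correlation, fry adjusted p = 0.0229). Without control replicates 2 and 3 and MFAP5 replicates 1 and 3, 2, 1, 2 and 3 of its members passed. The spike-in covariate left 7 and 2 genes higher on the 2 lists, with medians of 0.59 and 0.49. The 3 MFAP5 arrays in which both lists rose also had lower signals of all 12 adipocyte markers. Their beta-actin ratios of 3' to 5' probe sets lay above that of every control array. The group means of this ratio differed by 0.12 (exact permutation test, two-sided, p = 0.1).

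Of 25 measured interferon-response genes 8 rose (21 when adjusted over the list alone), and all 25 had a positive difference, with a median of 0.56. The list passed camera (adjusted p = 7.65e-21), had an adjusted p = 0.262 with an estimated correlation and missed the threshold with fry (adjusted p = 0.0559). Oasl2, Oas3 and Usp18, which interferon induces, rose by 1.01 ± 0.16, 0.86 ± 0.16 and 0.70 ± 0.13 (SE, n = 3 per group). Without control replicate 2 or 3 limma called none of its members, and without MFAP5 replicates 1 and 3 it called 4 and 2. It also called none with the spike-in level as a covariate, where the list median was 0.61 and 6744 probe sets had an unadjusted p under 0.05. Of 31 genes of endothelial activation and chemokines 6 rose and 1, Il1a, fell. The chemokine gene Cxcl1 rose by 1.57 ± 0.27, Ptgs2, an inducible cyclooxygenase, by 1.44 ± 0.23 and Nfkbia, the inhibitor kappa B alpha, by 1.17 ± 0.16. Adjusted over the list alone, 9 rose and 3 fell, and the median was 0.14 (camera adjusted p = 3.70e-05, adjusted p = 0.379 with an estimated correlation, fry adjusted p = 0.271). That median was 0.40, 0.31 and 0.045 without MFAP5 replicates 1, 2 and 3. With either control replicate 2 or 3 left out 1 gene of this list was higher, and with the spike-in covariate 2 were, with a median of 0.17. Without control replicate 1, 2 of its genes were lower, and none was without control replicate 2 or 3 or MFAP5 replicate 2. Lower adipocyte markers (12 of 12) and the higher beta-actin ratio were found in the same 3 arrays as the changes of both lists.

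Among 19 CREB targets 4 rose and 1 fell (9 and 1 when adjusted over the list alone): Sik1, a salt-inducible kinase, rose by 1.37 and the phosphatase gene Dusp1 by 0.90, while Ppargc1a, a coactivator of mitochondrial biogenesis, fell by 0.91. The CREB list median was 0.14 (camera adjusted p = 3.70e-05, adjusted p = 0.266 with an estimated correlation, fry adjusted p = 0.133). Of 47 genes of focal adhesions and stress fibres 2 rose (7 when adjusted over the list alone), Lpp, an actin-associated adhesion protein, by 0.50 ± 0.10 (adjusted p = 0.0275) and Enah, an actin regulator, by 0.88 ± 0.18 (adjusted p = 0.0361; 0.0593 with quantile normalization). The 8 probe sets of Lpp lay between 0.14 and 1.13 and 1 of them passed. Of the 6 probe sets of Enah 1 passed. Differences for Myh9, a non-muscle myosin, and Flna, filamin A, were 0.61 and 0.50 and missed the threshold (adjusted p = 0.0508 and 0.0585). The focal adhesion median was 0.12 (camera adjusted p = 4.85e-07, adjusted p = 0.244 with an estimated correlation, fry adjusted p = 0.0559). Of 44 calcium signalling genes 1 rose (1 when adjusted over the list alone), the calcium pump gene Atp2b1, by 0.58 ± 0.12. None of the 3 probe sets of Atp2b1 passed. With the probe set of largest SD for each gene Atp2b1 missed the threshold (limma adjusted p = 0.0709). The calcium list median was 0.047 (camera adjusted p = 0.00258, adjusted p = 0.302 with an estimated correlation, fry adjusted p = 0.271). Without control replicate 2 or 3 limma called none of the genes that rose on these 3 lists. The numbers higher on the CREB, focal adhesion and calcium lists were 5, 9 and 3 without control replicate 1, 1, 0 and 0 without MFAP5 replicate 1, 7, 0 and 0 without MFAP5 replicate 2, and 3, 1 and 0 without MFAP5 replicate 3. The spike-in covariate left 1, 1 and 0, with medians of 0.28, 0.13 and 0.086. With control replicate 1 left out a focal adhesion and a calcium gene were lower, as was a focal adhesion gene without MFAP5 replicate 3. Myh9 and Flna passed without control replicate 1 (adjusted p = 0.00698 and 0.0162), as they did with quantile normalization (0.0363 and 0.0422). The CREB median was 0.23 without control replicate 2 or MFAP5 replicate 1 and 0.076 without MFAP5 replicate 3. The calcium median was 0.015 without control replicate 1, 0.075 without control replicate 2 and 0.074 without MFAP5 replicate 2. These shifts too were between the MFAP5 and control arrays, which also differed in adipocyte markers and the beta-actin ratio but overlapped in the Gapdh ratio.

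Among 24 apoptosis and p53 genes Pmaip1 alone rose, with or without adjustment over the list alone. The list had a median of 0.080 (camera adjusted p = 0.00894, adjusted p = 0.354 with an estimated correlation, fry adjusted p = 0.280) and missed camera without MFAP5 replicate 3 (adjusted p = 0.0757); its median was 0.047 without control replicate 3 and 0.046 without MFAP5 replicate 3. Among 24 genes of the unfolded protein response none passed limma, over all genes or adjusted over the list alone, while 3584 of all genes had an unadjusted p under 0.05. That list passed camera as higher (adjusted p = 0.0348; adjusted p = 0.262 with an estimated correlation, fry adjusted p = 0.253) with a median of -0.0084 and a mean of 0.086. That median was between 0.0053 and 0.062 whichever sample was left out. The list missed camera without control replicates 2 and 3 and without MFAP5 replicates 2 and 3 (adjusted p = 0.0522, 0.0596, 0.0580 and 0.0729). Of 24 fibroblast markers the matrix gene Fn1, fibronectin, rose by 0.83 ± 0.14 and Pi16 fell by 0.93 ± 0.19 (adjusted p = 0.0336, and 0.0712 with quantile normalization; 3 rose and 2 fell when adjusted over the list alone). The fibroblast median was 0.19 (camera adjusted p = 3.33e-04, adjusted p = 0.532 with an estimated correlation, fry adjusted p = 0.264), and the list missed camera without MFAP5 replicate 1 (adjusted p = 0.0674). With control replicate 2 or 3 left out limma called no apoptosis or fibroblast gene; without control replicate 1 it called 5 genes of the unfolded protein response and 4 fibroblast genes as higher, with 2 apoptosis and p53 genes higher and 3 lower, and Pi16 was not past the threshold without MFAP5 replicate 2 or 3. Without MFAP5 replicate 1, 2 fibroblast genes were lower. With the spike-in covariate neither Pmaip1 nor Pi16 passed, and the apoptosis median was 0.063 and the fibroblast median 0.12. The adipocyte markers and the beta-actin ratio separated the same arrays.

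**Figure D2:**
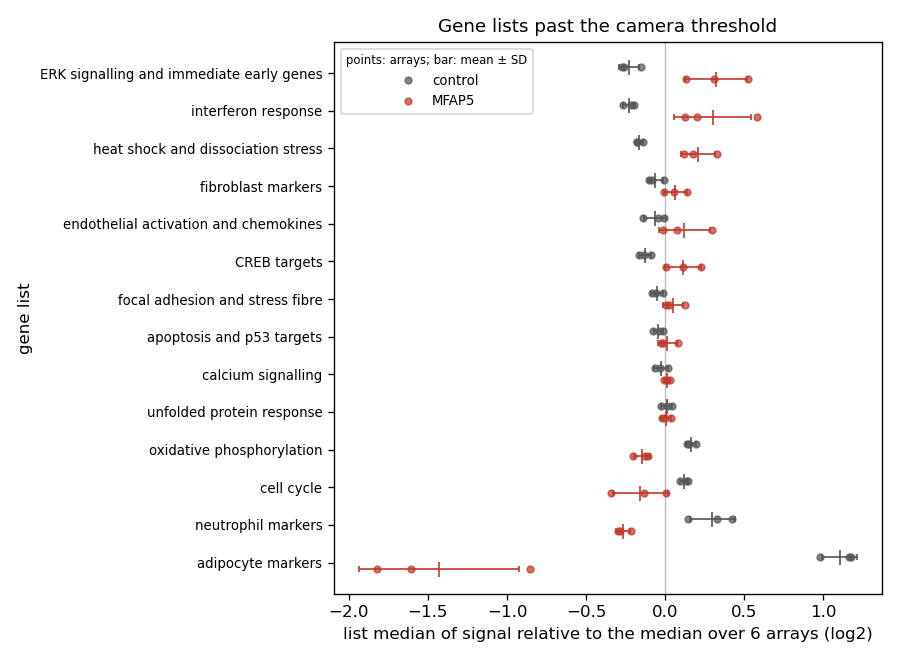
Median over the members of each gene list that passed camera, of the signal relative to each probe set's median over the 6 arrays (log2, horizontal axis), 1 row per list; points are arrays (3 control, 3 MFAP5), and bars the group mean ± SD. Adipocyte markers lie furthest apart, at 0.98 to 1.17 in the control arrays and -1.82 to -0.86 in the MFAP5 arrays.

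Of 17 basement membrane genes 4 fell: the collagen IV chains Col4a1 and Col4a2 at -2.22 ± 0.41 and -2.14 ± 0.33, Nid2, a nidogen, at -1.20 ± 0.16, and Col15a1 at -0.82 ± 0.13 (SE, n = 3 per group; adjusted p = 0.0242, 0.0110, 0.00473 and 0.0140). Col4a1 missed the threshold with a variance trend (adjusted p = 0.0656). Adjusted over the list alone, 5 fell and 1 rose, and the median was -0.0059 (camera adjusted p = 0.944). The list of tip cells and sprouting shares 7 members with it, and 5 of its 29 genes fell (6 when adjusted over the list alone), with Mcam, an adhesion molecule of endothelial and mural cells, at -2.24 ± 0.28 (camera adjusted p = 0.870, median -0.011). If control replicate 2 or 3 was left out, 1 basement membrane gene and 2 tip cell genes passed as lower, and without MFAP5 replicate 1 these counts were 2 and 3. Without control replicate 1, 2 basement membrane genes and 1 tip cell gene were higher, and without MFAP5 replicate 2, 1 tip cell gene was. With 1 sample left out the medians changed sign, between -0.065 and 0.017 for basement membrane and between -0.082 and 0.041 for tip cells. Of 36 endothelial markers 1 fell (3 when adjusted over the list alone), Nos3, the endothelial nitric oxide synthase, by 1.15 ± 0.18, and the list median was -0.18 (camera adjusted p = 0.0962; -0.093 without control replicate 2). Of 25 genes of endothelial junctions and permeability Cav2, a caveolin, fell by 1.01 ± 0.14 (3 when adjusted over the list alone; camera adjusted p = 0.220). Among 16 integrins Itga7, a laminin-binding subunit, fell by 1.40 ± 0.17, also when adjusted over the list alone, where 1 fell (camera adjusted p = 0.870). Of 16 mural cell markers 2 fell (4 when adjusted over the list alone), Mcam again and the potassium channel gene Kcnj8 at -0.90 (camera adjusted p = 0.164). Without control replicate 1, 8 endothelial markers, 6 junction genes and 2 integrins were lower and 1 junction gene higher; with control replicate 2 or 3 left out no endothelial marker and 1 mural marker were, and without MFAP5 replicate 2, 2 junction genes were. With a variance trend 3 endothelial markers and 3 junction genes were lower. The spike-in covariate left 1 basement membrane, 2 tip cell and 1 mural gene lower, with medians of -0.020, -0.037 and -0.11, and the endothelial median was -0.12. These decreases came in the 3 arrays in which all 12 adipocyte markers were lower and the beta-actin ratio was higher.

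Matrix proteases and their inhibitors moved in both directions: Adamts1 and Plat, tissue plasminogen activator, rose by 1.41 ± 0.14 and 1.09 ± 0.19, and Mmp8 and Mmp9, both also on the neutrophil list, fell, out of 31 genes (3 rose and 5 fell when adjusted over the list alone; camera adjusted p = 0.648). Of 30 genes of the TGF-beta and BMP response 2 fell, over all genes and adjusted over the list alone, Bmp4 at -0.74 and Smad6, an inhibitor of BMP signalling, at -0.97 (camera adjusted p = 0.257). Among 22 Notch pathway genes, 21 elastic fibre and microfibril genes and 31 genes of hypoxia and glycolysis limma called none over all genes, and 3, 0 and 0 when adjusted over the list alone, all 3 higher (camera adjusted p = 0.257, 0.832 and 0.176). Jag1, a Notch ligand, differed by 1.34 ± 0.36 (adjusted p = 0.0852), by 0.87 without MFAP5 replicate 2, and passed without MFAP5 replicate 3 (adjusted p = 0.0409). When control replicate 1 was left out, limma called 1 Notch gene higher and 2 lower, 2 elastic fibre genes higher and 2 lower, and 1 hypoxia gene higher. Without MFAP5 replicate 3, 1 Notch and 2 hypoxia genes were higher and 1 elastic fibre gene lower. A Notch gene was also higher without MFAP5 replicate 1, with a variance trend and with quantile normalization. Leaving out control replicate 2 or 3 left 1 higher and 1 lower protease gene, and 1 and 0 lower genes of the TGF-beta and BMP list, which had 1 lower gene without MFAP5 replicate 1 or 2. Protease genes were 4 higher and 2 lower without control replicate 1, 2 and 1 without MFAP5 replicate 1, and 3 and 4 without MFAP5 replicate 3. The TGF-beta and BMP list had 1 higher and 2 lower genes without control replicate 1, and 1 and 3 without MFAP5 replicate 3. With the spike-in covariate 1 protease gene was higher, and 1 gene of the TGF-beta and BMP list was lower. The 3 MFAP5 arrays in which these genes moved are those with lower signals of all 12 adipocyte markers and a higher beta-actin ratio.

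Of the other cell types, 3 of 29 macrophage markers fell, also when adjusted over the list alone: the scavenger receptor genes Marco and Cd36 at -1.59 and -1.52 and Chil3, a chitinase-like protein, at -1.40, while the median was 0.049 and the mean -0.12 (camera adjusted p = 0.190). The macrophage median was 0.080 without MFAP5 replicate 1 and -0.00012 without MFAP5 replicate 3. With median centring Cd36 and Chil3 missed the threshold (adjusted p = 0.0530 and 0.0528), and with quantile normalization Chil3 did (0.0807). Of 16 markers of NK and T cells Gzmb, granzyme B, fell by 0.81, also when adjusted over the list alone, where 1 fell (camera adjusted p = 0.549). For lymphatic endothelium (7 genes), dendritic cells (14), B and plasma cells (14), mast cells and eosinophils (15), erythroid cells and platelets (11), mesothelium (16) and epithelium (11) limma called no member, over all genes or adjusted over the list alone, and camera adjusted p lay between 0.265 and 0.944. Of 4 sex-linked transcripts Xist was higher by 0.73 ± 0.16 (adjusted p = 0.0477, and 0.0508 with median centring; 1 higher when adjusted over the list alone), and the Y-linked gene Kdm5d differed by -0.24 ± 0.11 (adjusted p = 0.281). Without control replicate 2 or 3 or MFAP5 replicate 1, 1 macrophage marker was lower and Gzmb did not pass, and Xist passed in no case but that of control replicate 1 left out. Without control replicate 1, 3 macrophage markers were higher and 2 lower, 2 NK and T cell markers were lower, and limma called 1 dendritic cell gene higher, 1 mast cell and eosinophil gene lower and 1 mesothelial gene each way. Without MFAP5 replicate 3, 2 macrophage markers were lower, and without MFAP5 replicate 2, 1 erythroid and platelet gene was higher. The spike-in covariate left 1 macrophage marker lower and no call of Xist. All 12 adipocyte markers were lower and the beta-actin ratio higher in the arrays of these changes too. Median and mean differed in sign for 7 of the 35 lists, among them the unfolded protein response list, which camera called higher. The mean and camera's direction differed for 7 of the 34 tested, and none of those 7 was called.

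Mfap5 itself differed by 0.091 ± 0.12 (adjusted p = 0.697), and the integrin genes Itgav and Itgb3 by -0.039 ± 0.095 and 0.64 ± 0.28 (adjusted p = 0.843 and 0.254). The 2 probe sets of Itgb3 differed, at 0.15 with overlapping groups and 1.12 without overlap (adjusted p = 0.817 and 0.0935), and its difference was 0.37 without control replicate 1 and 0.40 without MFAP5 replicate 2. With 1 sample left out Mfap5 lay between 0.034 and 0.19 and Itgav between -0.081 and -0.017. The endothelial genes Pecam1, Cdh5 and Kdr differed by -0.71 ± 0.22, -0.25 ± 0.15 and 0.24 ± 0.26 (adjusted p = 0.132, 0.379 and 0.631). Pecam1 passed without control replicate 1 (-0.95, adjusted p = 0.0195), Cdh5 was at -0.096 without control replicate 2, and Kdr lay between -0.094 without MFAP5 replicate 1 and 0.47 without MFAP5 replicate 2. Tnnc1, a troponin, differed by 0.017 ± 0.18, Lyz2, a myeloid lysozyme, by 0.049 ± 0.093, Col1a1, a fibrillar collagen, by 0.28 ± 0.12 and Ptprc, the leukocyte antigen CD45, by 0.62 ± 0.22 (SE, n = 3 per group; adjusted p = 0.968, 0.792, 0.257 and 0.172). Ptprc was at 0.36 without MFAP5 replicate 3, Tnnc1 ranged from -0.16 to 0.15 and Lyz2 from 0.017 to 0.080 with 1 sample left out. The ratio of 3' to 5' probe sets, which reports RNA integrity and amplification, was higher with MFAP5 by 0.081 (log2) for Gapdh and by 0.12 for beta-actin (exact permutation tests, two-sided, p = 0.4 and 0.1, the latter the smallest that 3 arrays against 3 can give). The Gapdh difference was 0.027 without control replicate 1, 0.12 without control replicate 2 and 0.052 without MFAP5 replicate 1.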

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

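The tests of repeats and of shares of higher calls in this part were chosen after the results had been seen. The array's control probe sets for B1 and B2 repeats, short interspersed elements found in many mouse transcripts, were not part of the comparison of genes and were higher with MFAP5 than in the control samples. The log2 differences were 0.33 and 0.23 for 2 B2 probe sets and 0.25 for a B1 probe set, and in each the 3 MFAP5 arrays lay above the 3 control arrays (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 can give).

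Higher calls were concentrated in probe sets with no gene name here: 364 of 419 called probe sets without a name were higher (86.9%), against 332 of 1034 with 1 name (32.1%; Fisher's exact test across probe sets, which are not independent, p = 6.46e-86). With quantile normalization the shares were still 51.0 percentage points apart, and with the spike-in level as a covariate 57.2 points, against 54.8. Centred values have no level, so quantile normalization could not remove an effect of the authors' scaling that depends on level. The spike-in level differed mainly between control replicate 1 and control replicates 2 and 3, so the covariate rests largely on that sample. Neither fit decides whether the authors' scaling or a hybridization difference is a cause. Without control replicate 1 the gap was 21.3 points, and with any other sample left out it was between 50.9 and 57.6. Nuclear or unspliced RNA in the MFAP5 samples stays open as a candidate explanation without an independent test: the 3 repeat probe sets that were higher prompted it, so they lend it no support. An effect of MFAP5 on such transcripts was not tested separately.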

How the results depend on the processing

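The spike-in covariate, control replicate 1 as sole control, the 50% of probe sets with the larger SD and the probe set with the largest SD per gene were chosen after the data had been seen. With quantile normalization, median centring and a variance trend the counts of probe sets and genes stayed within 1.5 times. The 1420, 1426 and 1436 called probe sets shared with the 1478 reported kept their direction. A variance trend leaves the differences themselves unchanged, so it could not alter a direction. Array weights gave 3043 higher and 3825 lower probe sets and 829 and 2220 genes, with control replicate 1 at a weight of 0.339 and control replicate 3 at 2.28. A minimum log2 difference of 1 left 310 and 369 probe sets and 44 and 209 genes, since it removes smaller changes. The unmoderated equal-variance statistic called 0 higher and 0 lower probe sets after adjustment, with 6433 at an unadjusted p under 0.05 against limma's 8420, so these probe set counts rest on limma's pooling of the spread; gene counts were not run without moderation. The spike-in covariate left 354 and 495 probe sets and 48 and 316 genes. Against control replicate 1 alone, whose spread was taken from the MFAP5 samples, limma called 0 probe sets and 0 genes, with 4187 probe sets at an unadjusted p under 0.05. The 50% with the larger SD gave 1609 higher probe sets, and the probe set with the largest SD 223 higher genes; for both, and for the covariate and weights, the cause was not tested.

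With each sample left out in turn, higher probe sets ranged from 90 to 2821, lower probe sets from 251 to 3369, higher genes from 14 to 760 and lower genes from 205 to 1914; the lists called higher by camera ranged from 9 to 11 and those called lower from 3 to 5. Differences in the ratio of 3' to 5' probe sets kept their sign. Camera with an estimated correlation called 0 lists higher and 0 lower, and fry called 2 higher. Of 224 comparisons of called lists with an alternative 190 kept their direction and call and 34 lost the call. Of 1372 comparisons for named genes 1050 kept their direction and stayed on the same side of the threshold, 300 lost the call, 14 gained it and 8 changed sign. The 1050 include comparisons of genes that were past the threshold in neither fit, so they are not all kept calls. Those 8 were all in genes not past the threshold: Tnnc1 at -0.13 with array weights, Tnnc1, Kdr and Acly with single samples left out, over which they ranged from -0.16 to 0.15, from -0.094 to 0.47 and from -0.022 to 0.22, Mfap5 at -0.021 against control replicate 1 alone, and Itgav at 0.19 with the probe set of largest SD.

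With the replicate number as a block there were 994 higher and 939 lower probe sets and 153 and 590 genes. With it 8 cell cycle genes were lower, against 3 without it, 2 macrophage markers were lower, 1 Notch gene and 2 apoptosis genes were higher, Xist was at an adjusted p of 0.0579, and Pecam1 and Myh9 passed (adjusted p = 0.0309 and 0.0447). The numbers were not taken as pairs, because deviations of same-numbered samples correlated at 0.21, 0.05 and 0.09 across probe sets, not all over 0.1. As a hint the other way, 5 of the 6 samples correlated best with their own number, and control replicate 2 correlated best with MFAP5 replicate 3. Of the 10 splits of the 6 samples into 3 and 3, 1, the real one, called as many as 1478 probe sets, and the highest of the others called 0; 10 splits are too few for a share under 0.05. Offsets, filters on level and the ratios of control probe sets with other offsets were not run, because centred values have no level; signal over background is unknown for the same reason.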

Other observations

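The tests with the spike-in level, of the chaperones and of the ERK feedback genes were chosen after the results had been seen; that of the additional adipocyte genes was written before their values had been seen. Among the genes with several called probe sets, 2 chosen after their values were seen were Malat1, a long non-coding RNA kept in the nucleus, higher by 1.17 ± 0.17 (SE, n = 3 per group; limma adjusted p = 0.00859) with 5 of 7 probe sets past the threshold, and Rbm39, an RNA-binding splicing factor, higher by 1.02 ± 0.16 (adjusted p = 0.0104) with 7 of 12. In an additional list of 18 adipocyte genes, of which 17 were measured, 11 fell, with a median log2 difference of -0.92. Gpd1, a glycerol-3-phosphate dehydrogenase, was at -2.20 ± 0.20, Agpat2, an enzyme of triglyceride synthesis, at -2.11 ± 0.12 and Pnpla2, adipose triglyceride lipase, at -1.80 ± 0.19, while Acly, ATP citrate lyase, differed by 0.094 ± 0.13 (adjusted p = 0.715). Of 12 measured heat shock chaperones 1 rose, and of 8 ERK feedback genes limma called none, with Spry2 at 0.49 ± 0.16 and Spry4 at -0.26 ± 0.11 (adjusted p = 0.141 and 0.243).

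Adipocyte genes were lower in every MFAP5 array than in any control array for all 12 list members, and the list's shift had an adjusted p = 0.262 with an estimated correlation. With the spike-in level as a covariate the list median was -2.67 (bootstrap interval over genes -4.45 to -1.88), against -2.81 without it. Genes of this list moved together (estimated correlation 0.77), so that interval does not measure the spread between samples. Spike-in levels hardly differed among the MFAP5 arrays and set control replicate 1 apart from control replicates 2 and 3. The covariate therefore rests largely on that sample and does not decide whether a hybridization difference is a cause. RNA of adipocytes in the control samples is a candidate explanation. Of the 17 additional adipocyte genes, 15 had all 3 MFAP5 values below all 3 control values, where 75% or more had been required. Among all probe sets 23.2% had groups without overlap, in either direction. These genes were listed after the first results had shown adipocyte markers lower. The count shows that further fat genes were lower, and it does not tell RNA of adipocytes from other causes. Absolute levels of these genes cannot be read from centred values, the labels name no sort or gate, none of the 12 is on another of the 35 lists, and at least 1, Pparg, is also known from endothelial cells. Whether such RNA came from tissue around the plug or from fewer fat cells in plugs with MFAP5 stays open and was not tested.

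Of the 34 genes on the immediate early list 13 were higher with MFAP5, and the list's shift had an adjusted p = 0.262 with an estimated correlation. With the spike-in level as a covariate the list median was 0.59 (bootstrap interval over genes 0.32 to 0.77), against 0.63 without it. As for the adipocyte genes, this covariate rests largely on control replicate 1, so a hybridization difference stays open. Stress during handling or dissociation stays open and has no independent test here: the heat shock chaperones had a median of 0.33 (0.10 to 0.41), above all of 10000 random lists of the same size, but all 12 measured are on the list of heat shock and dissociation stress whose shift was already known, so this value lends it no support. Signalling of MFAP5 through ERK stays open for the same reason, since all 8 ERK feedback genes are on the immediate early list itself. Their median was 0.080 (-0.26 to 0.26), at percentile 96.7 of random lists, where over 95 had been asked for.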
